A study of Mus musculus with 2 samples.

How the data were processed

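The deposited processed files, 1 filtered gene-by-barcode count matrix per library, were taken as the input, and the reads were not used here. The authors made the libraries with 10x 3' v3.1 chemistry from 6000 loaded cells each with a target of 3000 recovered cells, and sequenced them on a NovaSeq 6000 with paired reads of 150 bases at 100000 or more reads per cell. The UMI counts are those of Cell Ranger 8.0.1 per the file headers, aligned to mm10 per the submitters' processing notes. The 33696 features were matched to GENCODE M21, which holds 31961 of them (94.9%), and 1735 were not in it, so the annotation behind the counts is not given in the sources used here. 52 symbols were shared by several features. No column of the matrices was left unused (0 columns). The files held 21126 wild-type and 7766 Kif13b-/- barcodes, with 500 to 70683 and 501 to 118365 UMIs each. Both numbers are above the 3000 cells targeted and also above the 6000 cells loaded, so not every barcode can be a separate intact cell. 46.6% of wild-type and 20.2% of Kif13b-/- barcodes had under 2000 UMIs, and 715 (3.38%) and 133 (1.71%) had over 60% mitochondrial UMIs.

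Groups, comparisons, filters, 38 gene lists, markers of 24 cell types, the rule for naming genes and 17 other settings were fixed before the data were examined. Barcodes with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, 19832 in the wild-type and 7315 in the Kif13b-/- library. Doublets were scored with Scrublet within each library. Its automatic threshold marked 0 barcodes in both libraries and so had not worked, and the fallback, an expected share of 0.8% per 1000 barcodes, removed the highest-scoring 3146 (15.9%) and 428 (5.85%). The 16686 and 6887 barcodes left held 81976527 and 59853601 UMIs.

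Counts were scaled to 10000 per barcode and logged, 2000 variable genes were chosen with the library as batch key, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 1 gave the 40 clusters. No integration between libraries was applied. A cluster was given a class where at least 3 and at least 50% of the markers of that class were raised at least 2-fold and detected in at least 10% of its cells, where the mean log2 fold of the markers exceeded that of the next class by 1, and where it held at least 30 cells. These naming thresholds were set after the clusters were seen. Clusters left unnamed because under 50% of any class's markers were reached (7 clusters) held 23.7% of wild-type and 40.8% of Kif13b-/- barcodes. Clusters between endothelial cells and chondrocytes held 1.65% and 0.174%, between NK and T cells 1.08% and 1.35%, between adipocytes and fibroblasts 0.527% and 0%, between cardiac or skeletal muscle and pericytes 0.443% and 0.755%, between monocytes and chondrocytes 0.252% and 0%, and between endothelial cells and fibroblasts 0.234% and 0.494%. 5 clusters under 30 cells held 0.102% and 1.16%. Macrophage-like cells were clustered again at resolution 0.5.

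With 1 library per genotype no p values were computed. Within a class the UMIs of each gene were summed per library and divided by the total UMIs of the class, and log2 ratios used a prior count of 0.5. Intervals on sums are exact Poisson intervals, intervals on ratios are exact for 2 counts and intervals on shares are Clopper-Pearson intervals, all at 95%. They cover counting error only, not differences between animals. A zero count was given a bound from a floor of 3 counts. Expression was compared in the 5 classes with at least 50 cells in both libraries that the design named (macrophage, smooth muscle, fibroblast, endothelial and T cell) and over all barcodes. The list median was taken over members with at least 20 UMIs over both libraries, and placed, as a description of these libraries, among 10000 random lists drawn from 20 expression bins. Members at a ratio of 1.5 or more are called higher or lower. A gene that 2 lists hold counts under both.

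Kif13b, Mertk and 8 other genes were named in macrophages whatever their values. Besides these, the genes with the 12 highest and 12 lowest ratios in macrophages and 5 of each in other classes were named. They were drawn from genes with at least 50 CPM in the higher library and at least 50 UMIs. The 95% counting interval of such a gene also had to exclude equal levels in the libraries. Ribosomal protein, mitochondrial, haemoglobin, immunoglobulin and T cell receptor segment, sex-linked and uncharacterised Gm and Rik genes were left out, as were genes that another class held at over 10 times the level (possible free RNA). 1835 genes were eligible in macrophage-like, 1598 in smooth muscle-like, 1739 in fibroblast-like, 1412 in endothelial-like and 1083 in T cell-like cells. These are counts after all these conditions, the interval among them, and not counts of all expressed genes. From each list 2 to 4 members beyond the ratio were named, those with the most UMIs first.

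The lists in macrophage-like cells were efferocytosis receptors and bridging molecules, engulfment and phagosome maturation, don't-eat-me signals and shedding, lysosome, lipid-associated and foamy genes, tissue-resident genes, inflammatory genes, alternative activation and resolution, cholesterol efflux and liver X receptor targets, cholesterol synthesis, MHC class II, interferon response, monocyte recruitment and chemokine receptors, kinesin motors, KIF13B partners and scaffolds, matrix proteases and inhibitors, and 9 lists of metabolism, stress, death and proliferation. Those for other classes were smooth muscle contractile and modulation genes, fibroblast activation, fibroblast chemokines, collagens and elastin, endothelial adhesion, flow and barrier, lipid handling and mesenchymal genes, T cell activation and naive genes, erythrocyte RNA and sex-linked transcripts.

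Detection shares were also computed with each cell thinned to 1000 UMIs, which left out 400 wild-type and 127 Kif13b-/- macrophage-like cells. In a self-test on simulated counts from the macrophage-like sums, 50 of 50 genes changed by a fold of 2, 50 of 50 at 1.5, 50 of 50 at 0.5 and 50 of 50 at 0.667 were recovered. The changed genes had a mean of at least 50 CPM and the counts were Poisson, so the self-test holds no variation between cells or animals. The intervals covered the simulated ratio in 95.8% of 13943 genes. A list of 20 genes raised 1.5-fold gave a median of 0.58 at percentile 100, and 10 of 200 unchanged lists lay outside percentiles 2.5 to 97.5.

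Besides the 17 other settings fixed in advance (cell filters, depth, doublets, resolution, scaling within libraries, marker scores, TMM and other totals, weights of cells and sub-clusters, thinning, list filters, prior count and sub-cluster resolution), 10 were added after the data were seen. TMM factors were 1.01 and 0.994. The bulk macrophage experiment that the series design text describes was not analysed here, as its samples are not among those given. Counts per exon were not used here. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.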

Results

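Droplet-based single-cell RNA sequencing of the mouse aorta was compared between 1 wild-type library and 1 library labelled Kif13b-/-, referred to as the Kif13b-/- library. Kif13b encodes a kinesin motor that carries cargo along microtubules. The series title places the question in macrophages: whether KIF13B acts through MERTK, a receptor for dying cells, on efferocytosis (the engulfment of dying cells) in atherosclerosis. The title of the second library writes a homozygous knockout, whereas its genotype label reads knock down, and the strain, age, sex and diet of the animals were not given in the sources used here. With 1 library per genotype no test across animals could be made, and every 95% interval covers counting error only. The wild-type library held 93136569 UMIs (unique molecular identifiers, each standing for 1 captured transcript), with a median of 2162.5 per barcode, and the Kif13b-/- library held 64455003 UMIs, with a median of 5384.5. After filters and removal of putative doublets, 16686 wild-type and 6887 Kif13b-/- barcodes remained, with medians of 2385 and 5760 UMIs, 1314 and 2259 genes, and 5.82% and 7.76% mitochondrial UMIs.

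The targeted gene, Kif13b (ENSMUSG00000060012, chromosome 14, 64647265 to 64809617 on the plus strand of mm10, 6 annotated transcripts of up to 40 exons), was lower in the Kif13b-/- library but far from absent. Over all analysed barcodes it reached a level of 70.5 CPM (counts per 1000000 UMIs) in the wild-type library (5781 UMIs) and 43.8 CPM in the Kif13b-/- library (2619 UMIs), a log2 ratio of Kif13b-/- over wild-type of -0.69 (-0.76 to -0.62). In macrophage-like cells, Kif13b stood at 56.2 CPM (52.0 to 60.8, 647 UMIs) against 46.9 CPM (42.6 to 51.5, 440 UMIs), a log2 ratio of -0.26 (-0.44 to -0.08). The transcript was also lower in smooth muscle-like (59.4 against 46.9 CPM), fibroblast-like (66.1 against 41.8 CPM), endothelial-like (77.5 against 60.04 CPM) and chondrocyte-like cells (86.8 against 55.0 CPM), but not in monocyte-like cells (54.1 against 55.7 CPM, 35 and 16 UMIs, log2 ratio 0.07, -0.91 to 0.93). A Kif13b UMI was seen in 17.6% of wild-type and 19.7% of Kif13b-/- macrophage-like cells at median depths of 1970 and 3390 UMIs. With every cell thinned to 1000 UMIs these shares were 6.07% and 4.51%, leaving out 400 wild-type and 127 Kif13b-/- cells that were shallower. No class is known to lack Kif13b. Its lowest level among the classes plotted was in dendritic cell-like cells, at 24.8 and 16.9 CPM, with a UMI in 17.6% and 17.5% of cells at median depths of 9097.5 and 15408 UMIs.

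Counts from 3' ends may lie outside any deleted part of the gene, which the labels do not give, so they check nothing about the genotype label. In macrophage-like cells the log2 ratio stayed below 0 in all 13 settings run, from -0.91 with a cluster of mixed markers counted as macrophages to -0.16.

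**Figure D1:**
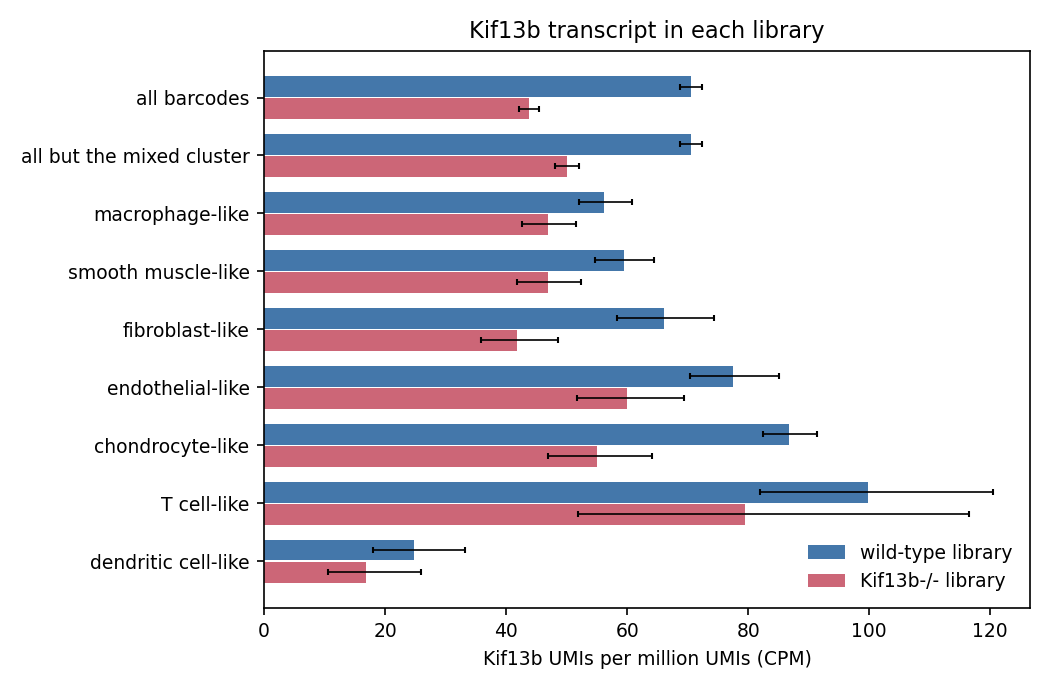
Kif13b CPM (horizontal axis) in all barcodes, in all barcodes but a cluster of mixed markers, and in 7 classes of each library, with bars for the summed level and lines for exact 95% Poisson intervals. The level is lower in the Kif13b-/- library in each, from 70.5 against 43.8 CPM over all barcodes to 24.8 against 16.9 CPM in dendritic cell-like cells.

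The cellular make-up of the aorta was compared next. Joint clustering gave 40 clusters, of which 22 were named as 13 classes from markers fixed in advance. Macrophage-like cells (C1qa, Csf1r, Adgre1) made up 14.6% of wild-type barcodes (14.1 to 15.2%, 2442 cells) and 17.6% of Kif13b-/- barcodes (16.7 to 18.5%, 1214 cells). Chondrocyte-like cells, defined by cartilage matrix genes such as Acan and Comp, were at 16.01% (15.5 to 16.6%) in the wild-type library and 4.79% (4.30 to 5.32%) in the Kif13b-/- library, a ratio of 0.299. Endothelial-like cells were at 12.4% against 7.55%, smooth muscle-like cells at 9.09% against 8.23% and fibroblast-like cells at 8.001% against 9.45%. T cell-like cells were at 2.70% (450 cells) against 0.726% (50 cells). The unnamed cluster 23, which carried all 9 T cell markers beside NK cell genes, held 1.08% (180 cells) against 1.35% (93 cells). Adipocyte-like cells were at 3.13% against 0.770%, while B cell-like cells were at 0.803% against 1.55%. Dendritic cell-like (1.09% and 1.16%), neutrophil-like (1.38% and 1.57%), monocyte-like (0.959% and 0.799%) and Schwann or glial-like cells (1.55% and 1.02%) were small classes in both libraries. Lymphatic endothelial-like cells were at 0.264% in the wild-type library (44 cells) and at 0 of 6887 barcodes in the Kif13b-/- library, with a 95% interval up to 0.0535%.

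Unnamed clusters held 28.0% of wild-type and 44.8% of Kif13b-/- barcodes. Clusters that reached under 50% of the markers of any class, a threshold set after the data were seen, held 23.7% and 40.8%. The largest of them in the Kif13b-/- library, cluster 7, held 1292 of its barcodes (18.8%, 17.8 to 19.7%) and 5 wild-type barcodes (0.030%), and combined genes of macrophages (Trem2, Apoe, C1qb, Lyz2), plasma cells (Ighg2b) and adipocytes (Cfd) with 15.3% mitochondrial UMIs. Cluster 1, the largest unnamed cluster of the wild-type library, held 9.98% and 6.32%. Cluster 8 (Crabp2, Cst6, Grem1) held 4.53% and 6.51% and cluster 10 (Itih4, Wnt16, Cxcl5) held 4.15% and 4.82%.

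Shares after tissue dissociation depend on which cells were recovered and called, and the Kif13b-/- barcodes were deeper in every class with cells in both libraries. Each library also held more analysed barcodes (16686 and 6887) than the 6000 cells loaded for it. Many wild-type barcodes therefore cannot be separate intact cells, and all cell numbers here are numbers of barcodes. In cluster 11, for example, wild-type barcodes of a median of 1354 UMIs held Acta2 at 2911 and Dcn at 2734 CPM. The chondrocyte-like ratio stayed between 0.216 and 0.444 in every setting run, but the macrophage-like ratio turned to 0.993 with genes scaled within each library and to 0.868 among barcodes of at least 5000 UMIs, where the endothelial-like ratio was 1.02, and the smooth muscle, fibroblast, Schwann and T cell-like ratios turned under 1 or more settings.

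**Figure D2:**
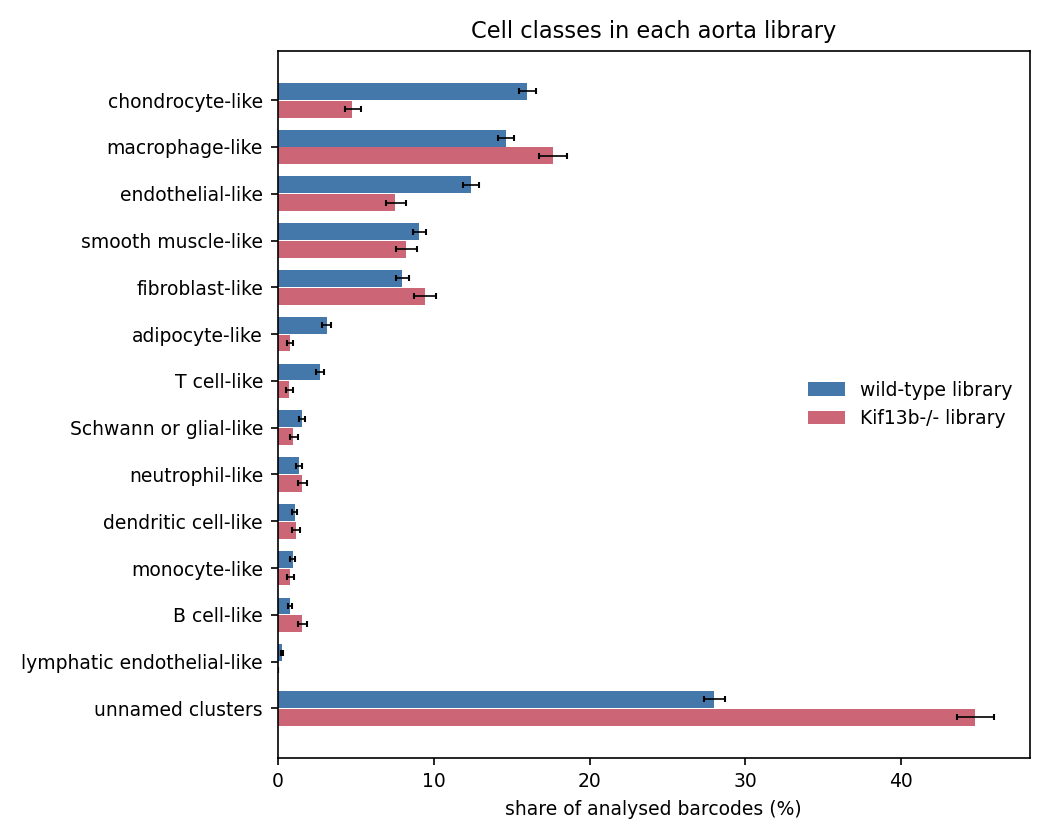
Share of analysed barcodes in percent (horizontal axis) for each cell class and for the unnamed clusters, with bars for the 2 libraries and lines for exact 95% Clopper-Pearson intervals. Chondrocyte-like cells stand at 16.01% in the wild-type and 4.79% in the Kif13b-/- library, and unnamed clusters at 28.0% and 44.8%.

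Macrophage-like cells were then compared for the genes of the study's question. Mertk was somewhat higher in the Kif13b-/- library, at 86.0 CPM (80.2 to 92.2, 807 UMIs) against 71.5 CPM (66.7 to 76.5, 822 UMIs) in the wild-type library, a log2 ratio of 0.27 (0.13 to 0.41). Axl, a receptor of the same kinase family, differed by 0.05 (-0.07 to 0.17), and the bridging molecules Gas6 and Pros1, which link these receptors to dying cells, by 0.03 and -0.05. Mfge8, another bridging molecule, differed by -0.15 (-0.23 to -0.07), though it was above 0 in 4 of 19 settings, up to 0.50. The engulfment receptor Lrp1 differed by 0.05. Cd47, the surface signal that holds back engulfment, differed by 0.07, whereas its receptor Sirpa was higher in the Kif13b-/- library at 257 against 199 CPM (0.37, 0.29 to 0.45), though not with cells classed by marker score (-0.0096) or with the mixed cluster counted as macrophages (-0.33), under which random lists also lay lower. Adam17, the protease that sheds MERTK from the cell surface, was slightly lower (-0.14, -0.23 to -0.04). The fixed list of efferocytosis receptors and bridging molecules had a median log2 ratio of 0.06 over 22 measured genes, with none higher or lower by a ratio of 1.5, at percentile 88.5 of 10000 random lists matched on expression. The engulfment and phagosome maturation list (25 genes) also had a median of 0.06, at percentile 90.5, with 1 gene lower, the engulfment adaptor Gulp1 (-0.87), which another class held at over 10 times the macrophage level. The list of don't-eat-me signals and shedding (9 genes) had a median of 0.07, at percentile 84.1.

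A Mertk UMI was seen in 18.3% of wild-type and 24.7% of Kif13b-/- macrophage-like cells, and in 5.22% and 10.3% of B cell-like cells at median depths of 2550 and 5338 UMIs, where Mertk is not known to be expressed. With each macrophage-like cell thinned to 1000 UMIs the shares were 7.54% and 5.80% and the log2 ratio of Mertk turned to -0.35. It was also below 0 with each cell weighing the same (-0.09) and under 3 other settings, so no direction of Mertk is read from these libraries. Among the named classes, Mertk was highest not in macrophage-like but in smooth muscle-like cells, at 170 and 164 CPM and in 53.7% and 70.4% of cells. How much of the macrophage-like Mertk count is smooth muscle RNA was not tested.

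Other macrophage programmes differed to varying degrees. The tissue-resident macrophage list (19 genes) was lower in the Kif13b-/- library, with a median log2 ratio of -0.83, below all 10000 random lists, and 11 genes lower by a ratio of 1.5 or more. Among them were the chemokines Pf4 (190 against 97.1 CPM, -0.96) and Ccl8 (213 against 52.2 CPM, -2.02), the mannose receptor Mrc1 (169 against 84.4 CPM) and the transglutaminase F13a1 (-0.83). Lipid-associated and foamy macrophage genes (20 genes) were shifted upward with a median of 0.29, above all random lists, though no member reached a ratio of 1.5 upward and the lipid-binding Fabp4, possible free RNA of endothelial cells or adipocytes, was lower (-0.81). Lysosomal genes (26 genes) had a median of 0.18 and mitochondrially encoded transcripts (13 genes) of 0.21, both above the middle 95% of random lists. Inflammatory macrophage genes (22 genes, median -0.07, percentile 7.90) included 4 chemokines lower in the Kif13b-/- library: Ccl4 (7427 against 4351 CPM, -0.77), Ccl2 (-0.67), Ccl7 (-0.96) and Cxcl10 (-0.90). Alternative activation and resolution genes went both ways (20 genes, median 0.00, percentile 60.8), with 6 lower, among them the haem-degrading enzyme Hmox1 (-0.91) and the lectin Clec10a (-0.89), and 2 higher, among them Chil3 (0.67). MHC class II genes (10 genes) had a median of -0.23, at percentile 1.99, and the unfolded protein response (14 genes) of -0.18, at percentile 0.880.

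The remaining macrophage lists lay within the middle 95% of their random lists. Cholesterol efflux and liver X receptor targets (15 genes) had a median of 0.02, with the transporter Abca9 lower (-0.66), and cholesterol synthesis (19 genes) of 0.05, with Insig1 lower (-0.59) and Fdps higher (0.60). Interferon response genes (28 genes) had a median of -0.04, with Ifit1 lower (-0.66) and Zbp1 and Oas2 higher (0.71 and 0.69). Kinesin motors (22 genes) had a median of 0.03, with Klc4 (0.66), Kif3c (0.79), Kif21b (0.59) and Kif5c (0.70) among 5 higher members, and KIF13B partners and scaffolds (15 genes) of -0.15, at percentile 2.86, with Cav1 (-0.78) and the endothelial receptor Kdr (-1.14), possible free RNA of endothelial cells, lower. Matrix proteases and inhibitors (19 genes, median -0.04) held 1 higher gene, the bone-degrading protease Ctsk (0.82), and 5 lower, among them Adamts1 (-0.90) and Mmp13 (-0.82). Monocyte recruitment and chemokine receptors (12 genes) had a median of 0.06, at percentile 86.0. Medians were 0.07 for hypoxia and glycolysis, 0.08 for nuclear oxidative phosphorylation genes, -0.05 for immediate early genes, -0.05 for heat shock, -0.08 for apoptosis and p53, -0.03 for pyroptosis, necroptosis and ferroptosis, and -0.13 for proliferation.

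RNA of other cell types was present in the macrophage-like class of both libraries, with Acta2 at 1063 and 1032 CPM and Dcn at 828 and 918 CPM, and cluster 3 held 52.9% of its wild-type cells against 28.2% of its Kif13b-/- cells, which lay mainly in clusters 9 (36.2%) and 14 (35.6%). Of the summed UMIs, cluster 9 held 63.8% in the wild-type and 71.2% in the Kif13b-/- library, and cluster 3 held 25.6% and 14.4%. The pooled levels thus mainly reflect cluster 9, where Acta2 was at 178 and 149 CPM and Dcn at 58.3 and 46.7 CPM. In cluster 3 Acta2 was at 2985 and 3416 CPM and Dcn at 1680 and 2815 CPM. In cluster 14 they were at 1755 and 3020 CPM and at 3410 and 3336 CPM. The tissue-resident list was below 0 in all 22 settings run (-1.14 to -0.28) and at -0.27, with 5 of 17 genes lower, once 98 wild-type and 11 Kif13b-/- cells of finer sub-clusters led by resident genes were left out. In contrast, the foamy list lay inside the middle 95% of its random lists with classes from marker scores (percentile 86.1), with the mixed cluster counted (71.9), with sub-clusters weighted alike (58.7) and in sub-cluster 4 alone (15.6). The lysosome list did so under the first 3 of these and lay below that range in sub-cluster 4 (-0.15), and the MHC class II list turned above 0 under 4 settings.

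**Figure D3:**
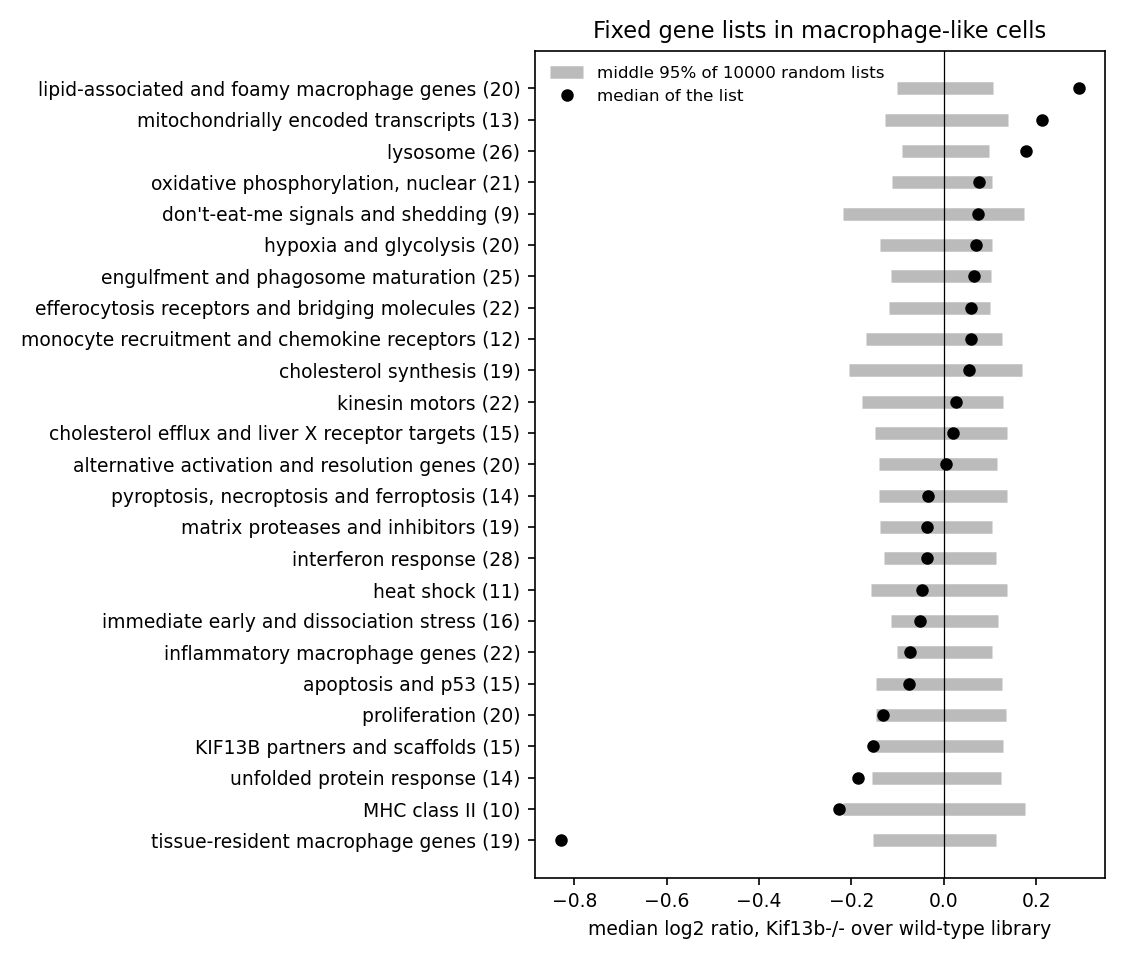
Median log2 ratio, Kif13b-/- over wild-type library (horizontal axis), of each fixed gene list in macrophage-like cells, with points for the list and grey bars for the middle 95% of 10000 random lists matched on expression and measured genes in parentheses. The tissue-resident list lies at -0.83, far below its bar, and the foamy list at 0.29 lies above its bar.

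Among 1835 genes eligible under the naming rule, the highest ratio in macrophage-like cells was that of the lysozyme gene Lyz1, at 44.3 CPM in the wild-type and 113 CPM in the Kif13b-/- library (1.35, 1.198 to 1.51). Then came Myo16 (0.88), Zmynd15 (0.84), Ctsk (154 against 272 CPM, 0.82), Olfml3 (0.79), the matrix protein thrombospondin Thbs1 (308 against 509 CPM, 0.72) and the monocyte markers Plac8 (104 against 172 CPM, 0.72), F10 (0.72) and Chil3, with Rin3 (0.70), Man1c1 (0.67) and Zdhhc14 (0.66). The lowest ratio was that of Ccl8 (-2.02, -2.17 to -1.88), followed by Dennd5b (-1.21), Fap (-1.14), the growth factor gene Kitl (-1.14), Pi15 (-1.06), the glypican Gpc6 (-1.01), Mrc1, the cholesterol hydroxylase Ch25h (-0.98), the chemokine Ccl6 (355 against 181 CPM, -0.97), Pf4, Ccl7 and Igfbp5 (-0.93). Fap, Pi15, Gpc6 and Igfbp5 are better known from fibroblasts and other stromal cells. Fap was, however, also among the leading genes of a finer macrophage sub-cluster led by Clec10a and Ccl8. That sub-cluster held 51 wild-type and 11 Kif13b-/- cells, with Dcn at only 26.3 and 49.6 CPM. All 12 lowest genes stayed below 0 in the 19 settings run for them. Of the 12 highest, Zmynd15, Plac8 and Rin3 stayed above 0 throughout, while Chil3 turned in 7 settings (down to -3.85 within sub-cluster 2) and Thbs1 in 5.

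**Figure D4:**
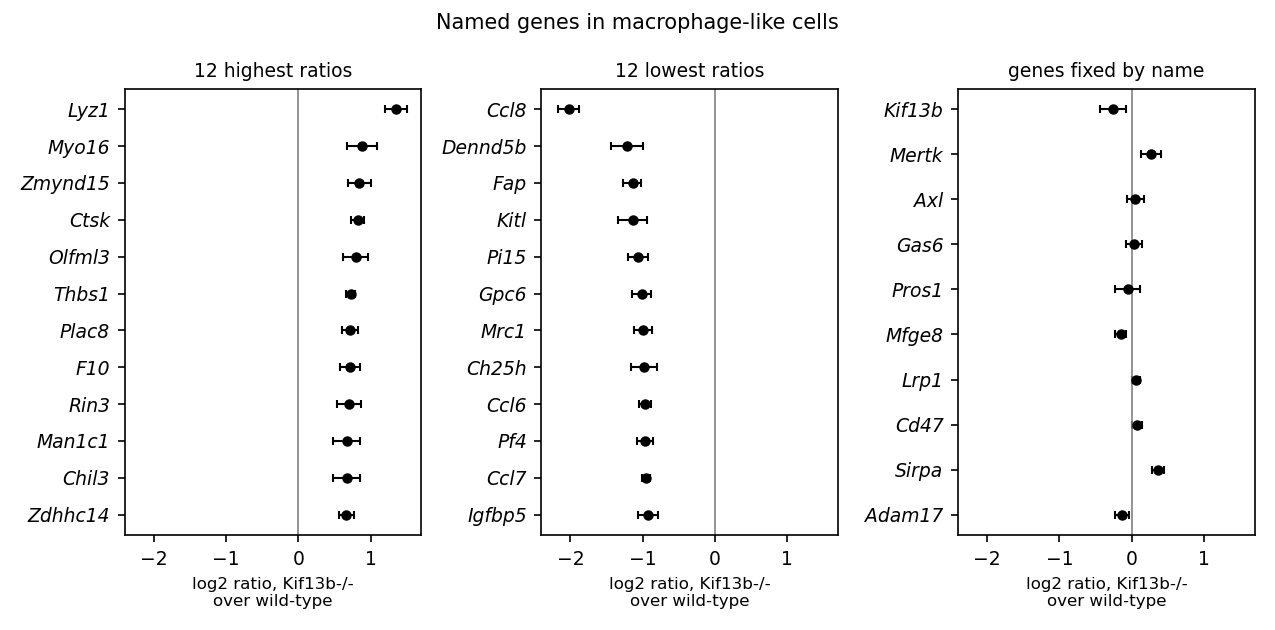
Log2 ratio, Kif13b-/- over wild-type library (horizontal axes), of the 12 genes with the highest and the 12 with the lowest ratios and of 10 genes fixed by name in macrophage-like cells, with points for the ratio of summed UMIs and lines for exact 95% counting intervals. Ccl8 lies lowest at -2.02 and Lyz1 highest at 1.35, and Mertk lies at 0.27.

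Macrophage-like cells were clustered again to describe the states each library held. Of 21 sub-clusters, 5 had at least 50 cells in both libraries. Sub-cluster 2, led by Atp6v0d2, Lpl and Gpnmb, genes of lipid-laden macrophages, made up 13.8% (12.5 to 15.2%) of wild-type and 23.6% (21.3 to 26.1%) of Kif13b-/- macrophage-like cells. Sub-cluster 4 made up 14.7% and 13.9%. Its leading genes Plac8, Chil3 and Ly6c2 are monocyte genes, but at a finer resolution 160 of its 529 cells lay in a sub-cluster led by these and 307 in a sub-cluster led by interferon and MHC class II genes (Ifit1, Rsad2, H2-Aa). Within sub-cluster 4, Mertk was at 47.1 and 21.1 CPM, Mrc1 at 398 and 204 CPM and Ccl8 at 596 and 146 CPM, and within sub-cluster 2 Mertk was at 96.8 and 128 CPM. A few cells carried most of the Ccl8 of sub-cluster 4. At a finer resolution, 51 wild-type and 11 Kif13b-/- cells in it, led by the resident genes Clec10a, Ccl8 and F13a1, held 342531 of its 2888435 wild-type UMIs. In these cells Ccl8 was at 4750 and 1886 CPM and Mrc1 at 1454 and 1012 CPM. Sub-clusters 1 (26.7% and 16.6%), 3 (15.5% and 13.7%) and 5 (2.95% and 21.7%) were led by genes of other tissues, such as Myh11 of smooth muscle, Comp of cartilage and Cst6 and Bpifb1, and had lower depth. A cycling sub-cluster (Top2a, Birc5) made up 3.19% and 1.40%. Sub-clusters 2 and 4 were deeper than sub-clusters 1, 3 and 5, with median depths of 9199 and 7677 UMIs in the wild-type and 14550 and 10995 UMIs in the Kif13b-/- library. At a finer resolution the share of sub-cluster 2 was 17.3% in the wild-type and 24.1% in the Kif13b-/- library.

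**Figure D5:**
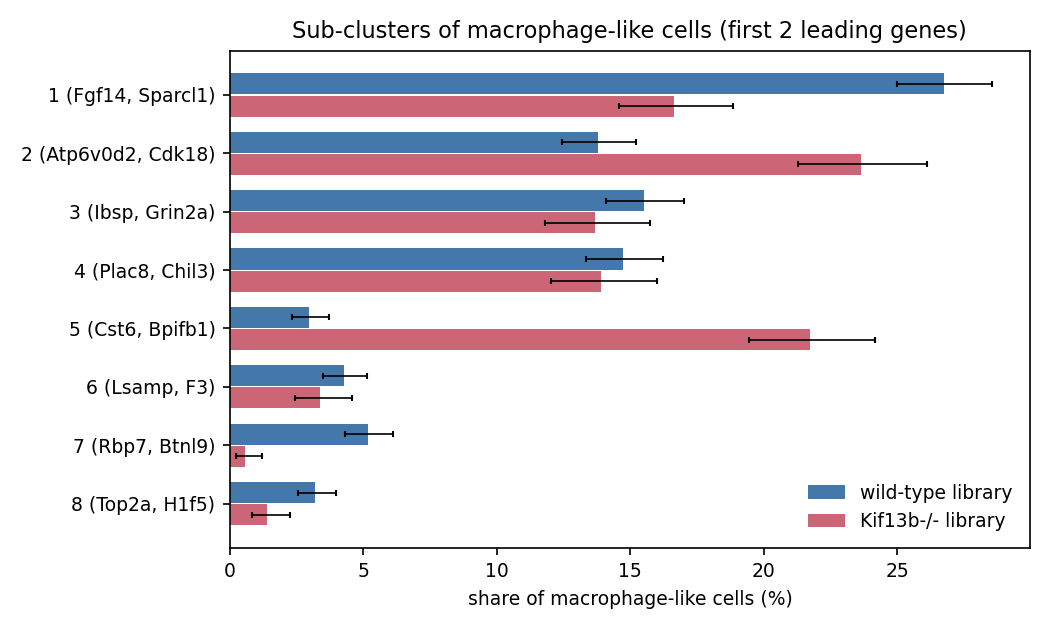
Share of macrophage-like cells in percent (horizontal axis) in the 8 largest sub-clusters, each with its first 2 leading genes, with bars for the 2 libraries and lines for exact 95% Clopper-Pearson intervals. Sub-cluster 2 stands at 13.8% in the wild-type and 23.6% in the Kif13b-/- library, and sub-cluster 5 at 2.95% and 21.7%.

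Smooth muscle-like cells (1516 wild-type and 567 Kif13b-/- cells, median depths 6613 and 11767 UMIs) were close in their contractile genes. The 18 contractile genes had a median log2 ratio of -0.04, at percentile 21.2, with none beyond a ratio of 1.5. The smooth muscle modulation list (22 genes, median 0.11, percentile 96.6) went both ways, with fibronectin Fn1 higher (1832 against 3031 CPM, 0.73) and Thbs1 (-0.67), the collagen Col8a1 (-0.62) and Spp1 (-0.69), possible free RNA of macrophages, lower. The highest ratios were those of the ephrin receptor Epha7 (1.06), the growth factor-binding Igfbp2 (1.00), the noncoding RNA Meg3 (0.99), Lsmem1 (0.97) and Tango6 (0.97). The lowest were those of the noncoding RNA Bc1 (-1.14), phospholamban Pln, which restrains calcium uptake (142 against 70.5 CPM, -1.01), the proteoglycan Aspn (329 against 164 CPM), the cytoskeletal adaptor Sorbs2 (1116 against 563 CPM, -0.99) and Nrip2 (-0.98). Heat shock genes (11 genes, median 0.19, percentile 99.8) and immediate early genes (16 genes, median 0.14, percentile 98.9), among them Hspa1b (0.63) and Jun (0.62), were shifted upward in the Kif13b-/- library, and KIF13B partners downward (14 genes, -0.17, percentile 0.620). Cluster 15 held 36.7% of the summed UMIs of the wild-type and 51.6% of those of the Kif13b-/- library. In cluster 6 alone, the larger in cells, the immediate early median turned to -0.10, the heat shock median was 0.08 and the partner median -0.08, all within random lists. There Tango6 (0.44), Lsmem1 (0.64), Pln (-0.64), Sorbs2 (-0.64) and Nrip2 (-0.59) were smaller in size.

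Fibroblast-like cells (1335 and 651 cells, median depths 1817 and 3410 UMIs) carried higher matrix, chemokine and cell cycle genes in the Kif13b-/- library. Collagens and elastin (23 genes) had a median log2 ratio of 0.32, above all random lists, with Col3a1 (0.66), fibrillin Fbn1 (0.60), Col8a1 (0.75) and Col5a3 (0.86) among 4 higher members. Fibroblast activation genes (18 genes, median 0.26) included Ltbp2 (1.05) and Cthrc1 (1.00) as higher and Tagln (-0.70), possible free RNA of smooth muscle, as lower, and fibroblast chemokines, complement and growth factors (18 genes, median 0.25) included complement C3 (0.60), Cxcl12 (0.76), Ccl19 (0.70) and Cxcl14 (1.05). Both lay above the middle 95% of random lists, as did matrix proteases and inhibitors (18 genes, median 0.28). Proliferation genes (18 genes, median 1.13) had 13 higher members, among them Stmn1 (1.08), Cenpa (2.07), Birc5 (2.36) and Top2a (1.73). Of single genes, Cxcl13, a chemokine that attracts B cells, was highest (11.3 against 117 CPM, 3.35, 2.93 to 3.84), followed by Nt5dc2 (2.27), the kinesin Kif26b (2.10) and the proteases Mmp12 (2.02) and Mmp13 (1.96). The lowest were the histone deacetylase Hdac9 (-1.60), Cytl1 (-1.56), the glypican Gpc3 (-1.52), the lipid kinase Dgkb (-1.44) and the potassium channel Kcnq5 (-1.33).

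Macrophage transcripts were also higher in this class, with Lyz2 at 286 and 528 CPM and C1qa at 52.8 and 88.2 CPM, and cluster 20, which held more of them than cluster 2, made up 14.9% and 20.6% of the cells. Smooth muscle transcripts were lower, with Acta2 at 1400 and 1003 CPM and Myh11 at 375 and 236 CPM. Dgkb stood at 522 CPM in wild-type smooth muscle-like and 57.2 CPM in wild-type fibroblast-like cells. In cluster 2 alone the proliferation median was 0.38, and in cells of at least 5000 UMIs the chemokine median was 0.07, the protease median 0.15, Cxcl13 was at 1.88, Mmp12 at 4.38, Hdac9 at -0.98, Dgkb at -0.69 and Kcnq5 at -0.62.

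Endothelial-like cells (2068 and 520 cells, median depths 1829 and 3561.5 UMIs) had higher lipid-handling and lower cell cycle genes in the Kif13b-/- library. Endothelial lipid handling (11 genes, median 0.39, above all random lists) had 5 higher members, among them Fabp5 (0.63), the lipoprotein receptor Scarb1 (0.85), lipoprotein lipase Lpl (0.72) and its anchor Gpihbp1 (0.80). Proliferation genes (18 genes, median -0.98, below all random lists) had 11 lower members, among them Stmn1 (-1.40), Top2a (-0.73) and Tpx2 (-1.37). Adhesion and activation genes (16 genes, median -0.06, percentile 20.1) included Cxcl12 as higher (0.93) and Sdc4 as lower (-0.84), flow and barrier genes (19 genes) had a median of -0.03, and endothelial to mesenchymal genes (15 genes) of 0.06. Igfbp2 was at 3.57 CPM in the wild-type and 64.9 CPM in the Kif13b-/- library (4.15, 3.52 to 4.93), followed by the matrix gene Vwa1 (1.55), the lipase inhibitor Angptl4 (1.28), the coagulation inhibitor Tfpi (1.21) and the apelin receptor Aplnr (1.17). The lymphatic genes Ccl21a (-6.19) and Mmrn1 (-3.50) were lowest, with Nts (-1.76), Dgkb (-1.43) and Stmn1. Cluster 19, led by the capillary genes Gpihbp1 and Cd300lg, held 16.6% of the summed UMIs of the wild-type and 37.0% of those of the Kif13b-/- library. In cluster 5 alone the lipid-handling median was -0.10, Aplnr was at -0.11, Tfpi at 0.0081, Vwa1 at 0.86, Nts at 0.59, Ccl21a at -3.06 and Mmrn1 at -1.78, while the proliferation median was -1.60 and the adhesion median 0.38.

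T cell-like cells could be compared with little precision, with 50 Kif13b-/- cells of a median of 2000 UMIs against 450 wild-type cells of 1615.5. The unnamed cluster 23 of T and NK genes, with 93 Kif13b-/- cells of a median of 6013 UMIs, was not part of the class, so effector genes such as Gzma are compared without it. Proliferation genes (11 genes, median -2.26, below all random lists) were lower in the Kif13b-/- library in all 11 members, among them Stmn1 (-2.88) and Top2a (-2.68), and T cell activation and effector genes (10 genes, median -0.76, percentile 0.240) had 5 lower members, among them the interleukin receptor Il2ra (-3.12) and the transcription factor Gata3 (-1.36). T cell naive genes (7 genes, median -0.07) went both ways, with Tcf7 (-2.28), Lef1 (-1.73) and Satb1 (-1.11) lower and Klf2 (0.68) and Il7r (0.59) higher. Immediate early genes (16 genes, median 0.64, above all random lists) had 8 higher members, among them Fos (1.02) and Egr1 (1.07), and the heat shock median was 0.16. The highest single genes, Tnn (2.78), Cst3 (2.58), Cst6 (2.54), Nos2 (2.43) and Gdf10 (2.32), are not T cell genes, and the fibroblast gene Dcn stood at 3218 and 8218 CPM in the class. Ly6d had 95 wild-type UMIs and 0 in the Kif13b-/- library, at least 9.57-fold lower against a floor of 3 counts, and Pclaf 86 and 0, at least 8.67-fold lower. Single UMIs of Fgf14 (-3.93, -9.83 to -1.98), the granule protease Gzma (-3.89, -9.79 to -1.94) and Tafa1 (-3.70, -9.60 to -1.74) were counted in the Kif13b-/- library. Tafa1 was a leading gene of smooth muscle-like cluster 15, and Fgf14 led macrophage sub-cluster 1 beside Myh11. With Acta2 at 2812 and 2048 CPM in the T cell-like class, their values may be smooth muscle RNA.

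Over all analysed barcodes, mitochondrially encoded transcripts (13 genes) were higher in the Kif13b-/- library, with a median log2 ratio of 0.50, above all random lists, and with mt-Atp6 (0.72) and mt-Co3 (0.81) among 5 members beyond a ratio of 1.5. This sum includes the mixed cluster with its 15.3% mitochondrial UMIs, and within classes the median was lower, at 0.21 in macrophage-like, 0.17 in smooth muscle-like, 0.12 in endothelial-like and 0.0028 in fibroblast-like cells. Proliferation genes (20 genes) had a median of -0.19, at percentile 0.630, and kinesin motors (23 genes) of -0.02, with Kif13b and Kif21a (-1.30) lower. Erythrocyte RNA (5 genes, mainly haemoglobins) summed to 796 UMIs in the wild-type and 15 in the Kif13b-/- library, a log2 ratio of -5.23 (-6.12 to -4.55), and the median of its genes, with 2 genes at 0 set to their bound, was -5.16. The sex-linked list (5 measured genes) had a median of -0.33, and no member differed by a ratio of 1.5. The Y-linked genes Ddx3y (11364 and 6591 UMIs) and Uty (6660 and 3866 UMIs) were well counted in both libraries. Xist, a transcript of female cells, had 11 and 7 UMIs, so both libraries carried the pattern of male cells.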

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

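The tests of the mixed cluster as free RNA and as several cells in 1 droplet were set before their values were seen, and the count of libraries per genotype was added only after the result was seen.

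A cluster that stood almost alone in the library labelled Kif13b-/- went against what was written down in advance for the make-up of the libraries. It held 18.8% of that library's barcodes and 0.030% of the wild-type barcodes, at a median of 7240 UMIs, with Acta2 at 3645 CPM, Dcn at 3234 CPM, Apoe at 5522 CPM and Lyz2 at 3147 CPM side by side, and with Kif13b at 15.2 CPM (12.9 to 17.7). Droplets of free RNA could give this, because at 3000 UMIs per barcode the median variance over mean of the 200 most abundant genes was 1.05, against 1.00 in a simulated common pool and 1.49 in smooth muscle-like, 1.94 in fibroblast-like and 2.02 in macrophage-like cells. This spread does not tell whether the same pool lies in other droplets. Cfd and Igkc were at 511 and 269 CPM in the cluster. In Kif13b-/- endothelial-like cells they were at 11.3 and 16.1 CPM beside Acta2 at 1911 CPM, so the RNA of other cell types there had a different make-up. Several intact cells of different types in 1 droplet did not match the values, since 6 class markers varied at 1.30 times their mean. A value of 3 or more had been set as its mark. For these markers the simulated common pool gave 1.03, smooth muscle-like cells 1.79, macrophage-like cells 11.8 and fibroblast-like cells 11.5. The genotype may also have altered the recovery of intact cells, which 1 library per genotype cannot tell apart, and a further library per genotype with its unfiltered barcodes would show whether such barcodes come with the genotype.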

How the results depend on the processing

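All values here are log2 ratios of the Kif13b-/- over the wild-type library in macrophage-like cells unless a share or share ratio is named, and the alternatives said to be added were chosen only after the result was seen. No paired analysis was possible because each genotype had 1 library and no labels pair them. For the main results that moved or turned, the cause was not tested.

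The counts given next are of values, with each result counted under every setting run for it, so they are not counts of separate results. The main results include the efferocytosis, foamy and tissue-resident lists, the Kif13b ratios, the macrophage-like shares and the chondrocyte-like share ratio. Of their values, 44 list, 17 gene, 6 share and 5 share ratio values stayed, 15, 5, 18 and 6 moved, and 4 list values and no gene values turned. Of the other values, 405 gene, 507 list, 61 ratio and 7 share values stayed, 238, 89, 42 and 1 moved, and 41 gene, 10 list and 15 ratio values turned.

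At Leiden resolution 0.5 the macrophage-like share was 18.0% in the wild-type and 20.4% in the Kif13b-/- library, and the smooth muscle share ratio was 1.28. At resolution 2 the shares were 8.77% and 12.4%, the fibroblast share ratio 0.883, the tissue-resident list -0.33, Chil3 -0.26 and Thbs1 -0.24.

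With at least 1000 genes and at most 10% mitochondrial UMIs the macrophage-like shares were 13.5% and 20.8%, Kif13b over all barcodes -0.47, Cd47 -0.0047, Chil3 -0.24 and Thbs1 -0.19. Share ratios were 1.51 for Schwann or glial-like, 1.23 for T cell-like, 1.33 for smooth muscle-like and 0.386 for chondrocyte-like cells. With at least 200 genes and at most 25% the Kif13b-/- macrophage-like share was 16.7%, the fibroblast share ratio 1.00, Chil3 -0.56 and Thbs1 -0.15. Without doublet removal the macrophage-like shares were 15.2% and 18.9%, the tissue-resident list -0.69, the T cell and fibroblast share ratios 1.27 and 0.947, Cd47 -0.0066, Chil3 -0.51 and Thbs1 -0.049.

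With at least 2000 UMIs in both libraries the macrophage-like shares were 9.60% and 12.2%, the tissue-resident list -0.36, the MHC class II list 0.21, Cd47 -0.036, Chil3 -1.05 and Thbs1 -0.20, and the share ratios were 1.11 for Schwann or glial-like and 0.241 for chondrocyte-like cells. With at least 5000 UMIs, which was added, the Kif13b-/- macrophage-like share was 12.5%, Mfge8 0.13, and the share ratios were 0.868 for macrophage-like, 0.216 for chondrocyte-like and 1.02 for endothelial-like cells.

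With each cell classed by its highest marker score the wild-type macrophage-like share was 9.08% and the chondrocyte share ratio 0.372. The tissue-resident list was then at -1.14, efferocytosis at -0.073, the foamy list at -0.026 and lysosome at -0.038, with Kif13b at -0.60, Mertk -0.0399, Cd47 -0.13, Mfge8 0.28 and Sirpa -0.0096. With genes scaled within each library the macrophage-like shares were 15.7% and 15.6%, and the share ratios 0.993 for macrophage-like, 0.444 for chondrocyte-like, 0.874 for fibroblast-like and 1.05 for smooth muscle-like cells.

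With each cell thinned to 1000 UMIs Mertk was at -0.35 and the tissue-resident list at -0.46. With each cell weighing the same Mertk was at -0.094 and the tissue-resident list at -0.56, and with list members of at least 100 UMIs that list was at -0.68. With sub-clusters weighted alike it was at -0.59, the MHC class II list at 0.0803, the foamy list at -0.0027, lysosome at -0.029 and Myo16 at -0.079. At sub-cluster resolution 1 the finer sub-clusters matched to sub-cluster 2 held 17.3% of wild-type macrophage-like cells.

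With the mixed cluster counted as macrophages, which was added, the Kif13b-/- share was 36.4%, the tissue-resident list -1.08, efferocytosis -0.20, the foamy list -0.16 and lysosome -0.25. Kif13b was then at -0.91, Mertk -0.31, Cd47 -0.23, Chil3 -0.11, F10 -0.067, Mfge8 0.50, Myo16 -0.073, Sirpa -0.33 and Zdhhc14 -0.20. Random lists matched to the foamy list lay between -0.52 and 0.13 there and between -0.32 and 0.08 with marker scores, so its median below 0 under these is no turn against other genes. With that cluster left out, also added, the share was 21.7%, Kif13b over all barcodes -0.49, and the share ratios 0.368 for chondrocyte-like and 1.12 for smooth muscle-like cells.

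Within sub-cluster 2 alone, which was added, the tissue-resident list was at -0.28, the MHC class II list at 0.33, the foamy list at 0.17, Cd47 at -0.00028 and Chil3 at -3.85. Within sub-cluster 4 alone, also added, the tissue-resident list was at -1.14, efferocytosis -0.11, the foamy list -0.039, lysosome -0.15 and MHC class II 0.051. There Kif13b was at -0.85, Mertk -1.14, Ctsk -0.87, Lyz1 -1.95, Man1c1 -0.34, Mfge8 0.11, Myo16 -0.37, Olfml3 -0.22 and Zdhhc14 -0.23.

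In the largest cluster of a class alone, which was added, the smooth muscle immediate early list was at -0.10, the endothelial lipid handling list at -0.10, and in endothelial-like cells Aplnr was at -0.11 and Nts at 0.59.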

Other observations

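The genes shared by several classes and all but the depth test of the patterns weighed here were chosen only after the result was seen.

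A small set of genes differed in the same direction in macrophage-like, smooth muscle-like, fibroblast-like and endothelial-like cells. Of 4834 genes compared, 12 had at least 20 CPM in the higher library of each class and a log2 ratio of at least 0.4 in size and of the same sign in all 4. The classes come from the same 2 libraries, so they are no replicates of each other, and no count without a difference was computed. The insulin-degrading enzyme gene Ide was at -0.84, -0.94, -1.23 and -0.93 in these classes, and the transcription factor gene Btaf1 at -0.59, -0.56, -1.09 and -0.46. Both lie on chromosome 19, Btaf1 at 36926079 to 37012752 and Ide at 37268743 to 37337852, as does Kmt5b at 3767421 to 3818303. Others of the 12 share a chromosome too, Sorbs2 and Hmox1 chromosome 8 and Bc1 and Rpl13a chromosome 7. No tally by location over the 4834 genes was made, so nothing is read from these places. The haem oxygenase Hmox1 was at -0.91, -1.42, -0.80 and -0.72, the adaptor Sorbs2 at -0.87, -0.99, -0.82 and -0.74, and the lipid kinase Dgkb at -1.32, -0.68, -1.44 and -1.43. Another class held over 10 times the level of Hmox1 in smooth muscle-like cells, of Sorbs2 in macrophage-like and fibroblast-like cells and of Dgkb in macrophage-like cells, where these values are possible free RNA. Values under that cut are not free of this doubt. Wild-type smooth muscle-like cells held Dgkb at 522 CPM, against 57.2 in fibroblast-like and 114 in endothelial-like cells. They held Mustn1 at 1449.5 CPM, against 172 in macrophage-like, 263 in fibroblast-like and 337 in endothelial-like cells. Bc1, Kmt5b, Nsa2, Mustn1 and mt-Nd4l (-0.75, -0.46, -0.91 and -0.81) were also lower, and mt-Nd3 (0.73, 0.76, 0.67 and 0.81) and the ribosomal protein gene Rpl13a (0.52, 0.50, 0.59 and 0.52) were higher.

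Among unnamed clusters, cluster 11 was close in share and a cycling cluster was not. Cluster 11, led by the migration receptor Ccr7 and the dendritic cell receptor Flt3, held 4.05% of wild-type and 3.50% of Kif13b-/- barcodes. It reached 4 of 9 dendritic cell markers, and held Acta2 at 2911 and 2393 CPM and Dcn at 2734 and 2990 CPM. Its share is therefore not read as that of an immune cell type. Cycling cells of cluster 28 (Top2a) held 0.965% and 0.348%.

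Kif13b transcript was found throughout the classes of the library labelled Kif13b-/-. RNA of wild-type cells carried over between the libraries does not account for it. Erythrocyte RNA, low but almost only in the wild-type library (9.71 against 0.25 CPM), had a log2 ratio of -5.23 (-6.12 to -4.55) where Kif13b had -0.69. Free RNA at the level of the mixed cluster, 15.2 CPM, is too low for the 47.4 CPM (42.7 to 52.5) in 491 macrophage-like cells of at least 5000 UMIs. The level in free RNA itself was not measured, and dendritic cell-like cells of this library held Kif13b at 16.9 CPM (10.5 to 25.9). Free RNA is thus not excluded across the classes. Transcript counted outside a deleted part of the gene may remain, with a log2 ratio of -0.49 without the mixed cluster, but no label gives such a part. The genotype label reads knock down, so a partial loss of the transcript is also open and was not tested. Counts per exon and a genotyping of the animals would help to tell these apart.

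Tissue-resident macrophage genes were lower in the library labelled Kif13b-/-, at a list median of -0.83. Low depth and free RNA could not account for all of it, as the median was -0.85 in cells of at least 5000 UMIs (681 wild-type and 491 Kif13b-/- cells), though it was smaller in size with at least 2000 UMIs (-0.36) and with each cell thinned to 1000 UMIs (-0.46), both below the middle 95% of random lists. A different mix of sub-clusters could be part of it, since the median was -0.59 with sub-clusters weighted alike and stood at -0.28 in sub-cluster 2 and -1.14 in sub-cluster 4. Fewer cells of the finer sub-clusters led by resident genes, 98 wild-type (4.01%) and 11 Kif13b-/- (0.906%), were not the whole of it, because without them the median was -0.27, still below the middle 95% of random lists (-0.16 to 0.12), and how large their part is stays open, since they were picked by the same list. The genotype itself cannot be told apart from the animal with 1 library per genotype, and several animals per genotype with counts of resident cells by flow cytometry would separate them.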
